A study of Mus musculus with 43 samples.

How the data were processed

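RNA was measured in 43 libraries from mouse full-grown oocytes and morulae. Per the labels' protocols, polyadenylated RNA was copied into cDNA with the SMART-Seq v4 kit and made into libraries with the Nextera XT kit. This chemistry does not mark the strand, so a gene and an overlapping antisense gene cannot be told apart. Each library of the catalytic-dead set was made from 10 pooled oocytes whose zona pellucida had been removed in acid, per the labels. How many oocytes or embryos went into the other libraries is not given in the sources used here. Groups were taken from the sample titles. In the second catalytic-dead library the tissue label says embryo, whereas its title and stage say full-grown oocyte, and it was kept with the oocytes.

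Per the submitters' processing notes, Trim Galore 0.6.4, STAR 2.7.3, STAR 2.7.6, RSEM 1.3.1 and featureCounts 1.6.0 were used on the builds mm10 and GRCm38. Which tool made which table is not given there. The authors deposited 3 tables, holding 35842, 35869 and 35842 gene symbols for the catalytic-dead set, the knockout oocytes and the morulae. The values of both oocyte tables are RPKM, reads scaled to transcript length and library size, as their deposited titles give them, and the libraries sum to between 622630 and 686690. The deposited morula table is also titled RPKM, but each of its libraries sums to between 999420 and 999920, as values scaled to a fixed total do. The deposited morula values were therefore taken to be TPM made by the authors, scaled to transcript length and to a fixed library total, and the test planned for RPKM was kept because it works on the log2 scale of either unit. The tables were normalised separately, so tests were run only within a table. Low values showed no whole-read steps, so the sequencing depth is unknown and no counting interval was computed. An exact 0 in such tables can be a failed estimate, so a gene without signal is described as listed at 0 and given no fold change.

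Before testing, 27 entries whose gene names had been turned into calendar dates were dropped from each oocyte table, and 0 from the morula table. Of 35869 symbols, 32401 matched a reference annotation of GRCm38.p6 directly and 33406 with synonyms. Coordinates are from that annotation, whose build is the one the notes name.

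Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend = TRUE). Genes needed a mean of at least 1 in at least 1 group of the table. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene was called changed at an adjusted p under 0.05. All groups of a table shared 1 estimate of the spread, and the replicate number was not a term. A fold change on this scale understates the change of genes with low values. Errors of fold changes are standard errors from limma, and errors of levels are SDs. Adjusted p-values of single genes are from limma throughout. The 7 comparisons were catalytic-dead against wild-type oocytes, and DKO against WT, TKO against WT and TKO against DKO in oocytes and again in morulae. These comparisons, the tests, the gene lists, the rule for named genes and most alternatives were set before the data were examined. The labels do not say whether replicates came from separate animals or litters, so p-values measure only the spread between these samples, which may be technical.

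The following lists were used: genes reported as imprinted through maternal H3K27me3 (noncanonical imprinting), genes imprinted through DNA methylation, subunits of PRC1, subunits of PRC2, MLL and COMPASS genes, Polycomb target developmental regulators, germline genes, oocyte and maternal-effect genes, DNA methylation genes, granulosa and cumulus cell markers, ovarian stroma and blood markers, genes of the 2-cell stage, pluripotency genes, trophectoderm genes, primitive endoderm genes, p53 and apoptosis genes, mitochondrial transcripts and X-linked housekeeping genes. They are from general knowledge, and some members of the first are less certain. Some genes stand in more than 1 list: Bmp7 is both a Polycomb target and noncanonically imprinted, Krt8 both a granulosa and a trophectoderm gene. A Y-linked list of 4 genes served only as a covariate in morulae. Each list with at least 5 tested members was tested with limma's camera at a fixed correlation of 0.01, adjusted over all 126 tests, and again with an estimated correlation. A member silent in WT is tested only where another group of its table reaches a mean of 1. Lists of mostly silent genes are thereby tilted towards rises, in counts, medians and camera tests. At the fixed correlation 27 tests were called, and with an estimated correlation 0 were. Camera sets a list against all other genes, so its direction can differ from the sign of the list's own median. Median, mean and test agreed in sign in every called list and differed in 24 of the other 99 tests, for which only counts and p-values are given. No called list changed the sign of its median under quantile or median-ratio scaling.

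Named genes follow a fixed rule: Pcgf1, Pcgf6, Kmt2b, Ring1 and Rnf2 always. Added to these are the 10 rising and 10 falling genes with the largest change among those called whose groups do not overlap (oocytes) or in which at least 8 of 10 libraries of each group lie beyond the median of the other (morulae), without predicted gene models. Also named are up to 4 members of each list with the smallest adjusted p, every called gene of the noncanonical list, and Xist in morulae. Genes of the Xlr, Vmn1r and Zscan4 families and Rnaset2a and Rnaset2b have near-identical copies, so their values are uncertain. Some genes that the rule names are not reported here.

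Overlaps between comparisons were tested with Fisher's exact test, two-sided, over genes tested in both tables. The return of DKO changes in TKO oocytes was counted against 20 simulated data sets in which TKO equals DKO and 20 in which TKO equals WT. Where comparisons shared control libraries, 50 draws of unchanged groups gave the correlation and covariance without an effect, and 20 the shared calls. Levels compared between groups of libraries used exact permutation tests, which go through every split of the libraries.

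The limma step was checked on simulated data: 10 draws per comparison with the real means and spreads, in which 200 genes were changed by known folds. The changed genes were drawn only from those above a level of 5, averaged on the log2 scale. Recovery of genes with lower values was not measured. Of genes changed 2-fold, the limma step recovered 73.6% in the catalytic-dead comparison, 95.4%, 94.6% and 96.3% in the oocyte comparisons in the order above, and 64.3%, 66.9% and 69.0% in morulae. At 1.5-fold it recovered 9.40%, then 73.1%, 65.8% and 69.0%, then 22.5%, 24.8% and 24.9%. False calls made up 10.9% of calls in the catalytic-dead comparison, above the nominal share, and between 4.41% and 6.54% in the others.

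Alternatives tried were a pseudocount of 0.1, no filter on low values, quantile normalization, median-ratio scaling, a threshold of at least 2-fold, eBayes without a trend, only the groups compared in the fit, the replicate number as a block, leaving out each library of the oocyte tables in turn and, in morulae, the Y-linked score as a covariate. After the data were seen, further alternatives were added: morulae without the libraries standing apart on the first principal component, only morula libraries with Y-linked transcripts, and oocytes without mitochondrial transcripts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.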

Results

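The dataset holds the RNA of mouse full-grown oocytes and of morulae in which parts of the Polycomb system had been removed. Polycomb repressive complex 1 (PRC1) places ubiquitin on histone H2A, PCGF1 and PCGF6 are subunits of its variant forms, and MLL2 (gene Kmt2b) is a histone H3K4 methyltransferase. The first set has 2 wild-type (PRC1-WT) and 2 PRC1 catalytic-dead (PRC1-CD) oocyte libraries. The second has 3 WT, 3 Pcgf1/6 double knockout (DKO) and 3 Pcgf1/6/Mll2 triple knockout (TKO) oocyte libraries. The third has 10 morula libraries each of WT, maternal DKO and maternal TKO. Oocyte levels are RPKM and morula levels are treated as TPM. The depth of the libraries is unknown. Between 10902 and 13086 genes per library had a value of at least 1.

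The deleted genes were examined first. Pcgf1 (GRCm38 chromosome 6, 83077552 to 83080855) stood at 1108 ± 39.9 RPKM in WT oocytes, 12.3 ± 1.47 in DKO and 12.2 ± 1.52 in TKO (SD, n = 3 each). It fell by 6.39 ± 0.10 on the log2 scale in DKO (limma adjusted p = 1.60e-10) and by 6.40 ± 0.10 in TKO. Pcgf6 (chromosome 19, 47033617 to 47050939) was lower too, at 57.1 ± 2.77 RPKM in DKO and 72.2 ± 9.86 in TKO against 154 ± 5.65 in WT. Its log2 changes were -1.41 ± 0.09 and -1.09 ± 0.09. Kmt2b (chromosome 7, 30568855 to 30589056) fell in TKO, from 4.85 ± 0.377 RPKM in WT to 1.14 ± 0.148 (log2 change -1.45 ± 0.11, adjusted p = 5.98e-06). In DKO Kmt2b stood at 3.90 ± 0.315 (-0.26 ± 0.11, adjusted p = 0.106). Rnf2, the main catalytic subunit of PRC1, stood at 38.0 ± 1.22 RPKM in WT, 38.5 ± 2.43 in DKO and 33.6 ± 1.91 in TKO, and its relative Ring1 stayed below 0.2 RPKM in every library of this table and was not tested. In the PRC1-CD set the RNA of the complex is not a check of the labels, because the mutation acts on activity. There, Rnf2 stood at 55.2 ± 11.1 RPKM in PRC1-WT and 57.0 ± 19.98 in PRC1-CD, Ring1 at 3.20 ± 0.0636 and 3.09 ± 0.948, Pcgf1 at 1292 ± 82.4 and 1505 ± 132, Pcgf6 at 172 ± 15.3 and 226 ± 28.3, and Kmt2b at 4.96 ± 0.0283 and 3.44 ± 0.0424 (n = 2 each). None of these 5 passed the test.

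**Figure D1:**
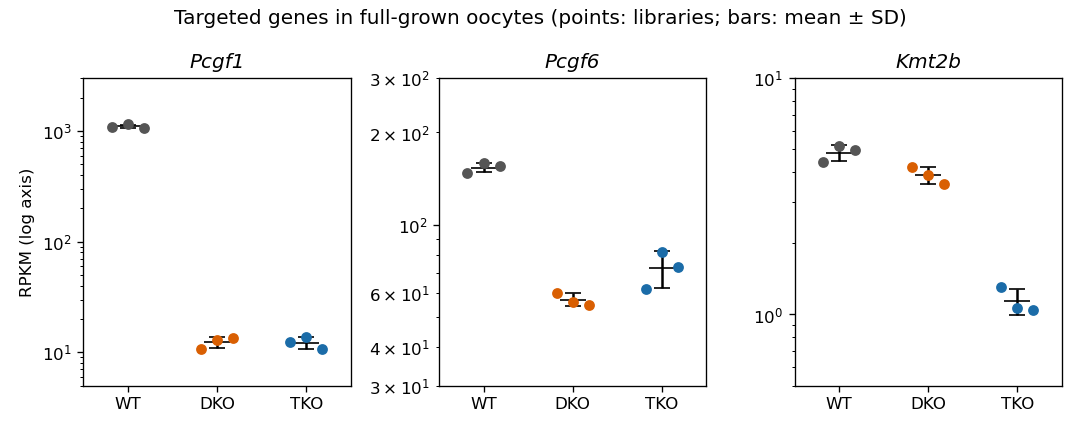
RPKM (log axis) of Pcgf1, Pcgf6 and Kmt2b in each WT, DKO and TKO oocyte library, with the mean and SD of each group. Pcgf1 lies at 1077 or more in the WT libraries and at 13.7 or less in the mutant ones, and Kmt2b lies at 1.31 or less in TKO.

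Oocytes without PRC1 catalytic activity were compared with PRC1-WT oocytes to ask which transcripts depend on that activity. Mt1, which encodes a metal-binding metallothionein (chromosome 8, 94178883 to 94180327), rose most, from 1.57 ± 0.00707 to 648 ± 144 RPKM (log2 change 7.97 ± 0.19, n = 2 each, adjusted p = 1.18e-05). Tmsb4x, an actin-sequestering thymosin, rose by 6.47 ± 0.38 and the placental gene Plac1 by 6.18 ± 0.27, from 2.08 ± 0.912 to 221 ± 62.3 RPKM. The germ-cell RNA-binding gene Rbm46 rose by 4.61 ± 0.20 and the cell-surface gene Cd47 by 4.42 ± 0.21, and Dapl1, Tceal8, Ly6g6e, Stambpl1 and Amigo2 completed the top 10, with changes between 4.14 and 4.93. Hjurp, the chaperone that deposits the centromeric histone, fell by 2.36 ± 0.23 to 4.97 ± 1.03 RPKM. Larger falls were seen for the defensin gene Defb41 (-5.33 ± 0.17), Rnaset2b (-4.54 ± 0.44) and the amino acid transporter Slc7a9 (-3.17 ± 0.38). The vomeronasal receptor genes Vmn1r132, Vmn1r112, Vmn1r139 and Vmn1r157 were lower as well, and the last 3 share identical values, so their reads cannot be assigned to a single copy. Erdr1 and Snora47 fell as well (-2.49 ± 0.25 and -2.28 ± 0.29).

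Of 114 Polycomb target regulators 37 passed the filter in the PRC1-CD set, and of these 30 rose and 1 fell (30 and 2 adjusted over the list alone). A target silent in PRC1-WT passes the filter only by reaching a mean of 1 in PRC1-CD, so the share of risers is partly set by the filter. The list passed camera (adjusted p = 2.72e-12), with adjusted p = 0.483 with an estimated correlation. Pax6 rose by 3.22 ± 0.18, Hoxd1 by 2.94 ± 0.18 and Irx2 by 2.92 ± 0.17, all homeobox genes of embryonic patterning. Of 31 genes imprinted through maternal H3K27me3, 12 passed the filter, with the same limit. Of these 10 were higher, 0 lower and 2 did not pass the test (11 higher adjusted over the list alone). For this list the adjusted p was 3.59e-06, and adjusted p = 0.773 with an estimated correlation. The 10 were Rbms1 (3.19 ± 0.21), Smoc1 (2.32 ± 0.16), Enc1 (2.09 ± 0.16), Sall3 (2.09 ± 0.17), Hunk, Bbx, Runx1, Bmp7, Etv6 and Platr20, the last by 0.81. Germline genes were split between 16 that rose, 1 that fell and 20 that did not pass (16 and 2 adjusted over the list alone; adjusted p = 0.00159, and adjusted p = 0.599 with an estimated correlation). Among them the meiotic chromosome axis gene Hormad1 rose by 3.69 ± 0.17, the synaptonemal complex gene Syce1 by 3.43 ± 0.18, and Meioc and Mael by 2.82 ± 0.19 and 1.83 ± 0.15.

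Trophectoderm genes had 9 higher and 1 lower of 21 (10 and 2 adjusted over the list alone), led by Plac1, Krt8 (4.11 ± 0.26), Tfap2a (2.13 ± 0.18) and Ly6a (1.83 ± 0.16). That list passed with adjusted p = 0.00355, and adjusted p = 0.599 with an estimated correlation. Granulosa and cumulus markers rose beside them, with 7 of 10 higher (8 adjusted over the list alone; adjusted p = 0.00627, and adjusted p = 0.706 with an estimated correlation). The follicle-stimulating hormone receptor gene Fshr rose by 3.37 ± 0.23 from 0.55 to 15.3 RPKM, Ptgs2 by 2.46 ± 0.18 and Cyp11a1 by 1.23 ± 0.25. Vim, Gja1, Inhba and Krt18, abundant in granulosa cells and named after their values were seen, were at 0.51 RPKM or less in PRC1-CD. All 4 were higher there than in PRC1-WT: Vim at 0.51 against 0.055, Gja1 at 0.34 against 0.055, Inhba at 0.14 against 0.115 and Krt18 at 0.11 against 0.015. Genes of the 2-cell stage had 7 of 15 higher and 0 lower, both over all genes and adjusted over the list alone (adjusted p = 0.0170, and adjusted p = 0.773 with an estimated correlation). Zscan4c, Zscan4f and Zscan4d, near-identical copies of 1 family, rose by 2.56 ± 0.21, 1.70 ± 0.18 and 1.65 ± 0.20, and Obox6 by 1.14 ± 0.21. Primitive endoderm genes had 6 of 12 higher and 1 lower (8 and 1 adjusted over the list alone; adjusted p = 0.0419, and adjusted p = 0.773 with an estimated correlation), among them Gata6 (1.73 ± 0.17) and Gata4 (1.06 ± 0.19).

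The other lists were not called in PRC1-CD oocytes. In the p53 and apoptosis list 7 of 21 rose and 0 fell (adjusted p = 0.134), with Pmaip1 and Fas up by 2.62 ± 0.17 and 2.78 ± 0.25. Of 19 genes imprinted through DNA methylation, 4 rose and 1 fell (adjusted p = 0.586), and the risers Phlda2 (3.37 ± 0.29), Igf2 (3.06 ± 0.18) and Cdkn1c (2.05 ± 0.20) lie in neighbouring imprinted domains on chromosome 7. Among 49 oocyte and maternal-effect genes 2 rose, the early follicle transcription factors Sohlh1 (3.17 ± 0.17) and Sohlh2 (2.78 ± 0.34), and 0 fell (adjusted p = 0.322). Of 31 PRC1 subunits Bcor (2.23 ± 0.21), Pcgf5 (1.23 ± 0.19) and Cbx8 (0.89 ± 0.15) rose (adjusted p = 0.994). The PRC2 list had 0 of 13 called (adjusted p = 0.307), and in the MLL and COMPASS list only Kmt2a passed of 21 (adjusted p = 0.0867). Dnmt1 and Dnmt3a fell by 0.64 ± 0.15 and 0.65 ± 0.17 among 17 DNA methylation genes (adjusted p = 0.577; 0 fell adjusted over the list alone). Counts higher and lower were 5 and 2 of 18 for pluripotency genes (adjusted p = 0.577; 4 and 4 with quantile normalization), 11 and 1 of 49 for X-linked housekeeping genes (adjusted p = 0.285), 2 and 0 of 5 for stroma and blood markers (adjusted p = 0.369) and 0 and 0 of 13 for mitochondrial transcripts (adjusted p = 0.518). The mitochondrial share of the total was 1.71 ± 0.562% in PRC1-WT and 1.63 ± 0.210% in PRC1-CD.

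In all, 2309 genes were higher and 750 lower in PRC1-CD among 13376 tested, and 1415 and 217 of these by at least 2-fold. With quantile normalization the counts were 1608 and 1538 and the median log2 change of all genes moved from 0.04 to -0.08, so the excess of higher genes depends on the scaling. The total of 3059 became 1325 without PRC1-WT replicate 1, 1238 without PRC1-WT replicate 2, 1543 without PRC1-CD replicate 1 and 1352 without PRC1-CD replicate 2.

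DKO oocytes were compared with WT oocytes to ask what the PCGF1 and PCGF6 forms of the complex contribute. Mt1 again rose most, from 2.78 ± 0.0866 to 681 ± 38.2 RPKM (log2 change 7.49 ± 0.11, n = 3 each, adjusted p = 1.60e-10). Rbm46 rose by 4.67 ± 0.19, the homeobox gene Lbx2 by 3.87 ± 0.14, Syce1 by 3.84 ± 0.12 and Pthlh, which encodes a parathyroid hormone-related protein, by 3.57 ± 0.16. Lbx2 (chromosome 6, 83086365 to 83088243) lies near the deleted Pcgf1, so an effect of the altered locus on it cannot be told apart. Phlda2, an imprinted gene that restrains placental growth, rose by 3.47 ± 0.18 from 15.4 ± 4.27 to 178 ± 25.9 RPKM, and Gsto1, Xlr and Rnaset2b were also in the top 10. Below Pcgf1, the largest falls were those of BC052688 (-3.79 ± 0.51), Iqcf1 (-3.23 ± 0.80), the claudin gene Cldn15 (-2.71 ± 0.18) and the zinc finger gene Zfp708 (-2.62 ± 0.31). Nlrp4e fell by 2.13 ± 0.10, from 43.8 ± 3.02 to 9.25 ± 1.33 RPKM, and Vmn1r132, Msmp, Zscan4d and Wfdc15a had log2 changes between -2.38 and -1.97. Rnaset2b and its copy Rnaset2a, named because of their shared reads, moved in opposite directions, by 4.53 ± 0.31 and -0.33 ± 0.06.

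Of 114 Polycomb targets 26 passed the filter in these oocytes, and in DKO 20 of them rose and 1 fell (21 and 1 adjusted over the list alone). Targets silent in WT pass only by reaching a mean of 1 in DKO or TKO, so the share of risers is partly set by the filter. Camera gave adjusted p = 1.89e-09, and adjusted p = 0.231 with an estimated correlation. Hoxd8 (2.43 ± 0.14), Hoxd1 (2.18 ± 0.13) and Irx2 (2.05 ± 0.13) rose. Of the 31 genes imprinted through maternal H3K27me3, 11 passed the filter, with the same limit. Of these 8 rose and 0 fell, and the counts were the same adjusted over the list alone (camera adjusted p = 6.35e-06, and adjusted p = 0.231 with an estimated correlation). They were Rbms1 (2.77 ± 0.17), Sall3 (2.07 ± 0.18), Bmp7 (1.59 ± 0.13), Bbx (1.53 ± 0.12), Epas1, Enc1, Platr20 and Etv6, the last by 0.70. In the p53 and apoptosis list 12 of 21 rose and 0 fell (12 and 1 adjusted over the list alone; adjusted p = 0.00205, and adjusted p = 0.265 with an estimated correlation). Atf3, a stress-response transcription factor, rose by 1.56 ± 0.20, the pro-apoptotic gene Bcl2l11 by 1.08 ± 0.13 and Trp53inp1 by 0.66 ± 0.07, and Btg2 rose too.

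The remaining lists were not called in DKO oocytes. Germline genes went both ways, with 14 higher and 5 lower of 35 (adjusted p = 0.130), and Syce1, Meioc (3.02 ± 0.21), Sycp3 (2.10 ± 0.15) and Sycp1 (1.55 ± 0.13) were among those that rose. Oocyte and maternal-effect genes had 4 higher and 8 lower of 49 (adjusted p = 0.285), with Sohlh2 and Sohlh1 up by 3.24 ± 0.14 and 1.92 ± 0.32 and Tle6 down by 0.40 ± 0.07. Zscan4d, Zscan4a and Zscan4f fell (-2.03 ± 0.16, -1.18 ± 0.17 and -1.54 ± 0.25) in the 2-cell list, which had 3 higher and 5 lower of 10 (adjusted p = 0.322). Trophectoderm genes had 8 higher and 3 lower of 18 (adjusted p = 0.134), Krt8 rising by 2.85 ± 0.29 and Gata3 falling by 1.31 ± 0.16. Genes imprinted through DNA methylation had 4 higher and 1 lower of 18 (adjusted p = 0.577), the higher ones being Phlda2, Igf2 (2.38 ± 0.22), Cdkn1c (1.93 ± 0.13) and Zdbf2 (1.17 ± 0.14). Of 30 PRC1 subunits 4 were higher and 3 lower (adjusted p = 0.586; 3 and 3 with quantile normalization), with Bcor up by 2.36 ± 0.12 and Pcgf5 by 0.99 ± 0.14. Granulosa markers had 5 higher and 2 lower of 10 (adjusted p = 0.500; 3 and 3 with quantile normalization), among them Krt8 up and the aromatase gene Cyp19a1 down by 0.60 ± 0.09. Higher and lower counts were 2 and 0 of 10 for primitive endoderm (adjusted p = 0.130), 6 and 4 of 17 for pluripotency (adjusted p = 0.548), 12 and 5 of 46 for X-linked housekeeping genes (adjusted p = 0.518; 10 and 9 with quantile normalization, 9 and 8 with median-ratio scaling), 2 and 2 of 16 for DNA methylation genes (adjusted p = 0.919) and 0 and 2 of 13 for PRC2 (adjusted p = 0.406). They were 1 and 1 of 21 for MLL and COMPASS genes (adjusted p = 0.289), 1 and 1 of 5 for stroma and blood markers (adjusted p = 0.484) and 0 and 0 of 13 for mitochondrial transcripts (adjusted p = 0.165).

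Among 12873 genes tested in DKO oocytes, 2251 were higher and 1450 lower, and 507 and 173 of these by at least 2-fold. The share of higher genes was 60.8% of calls, but 47.3% with quantile normalization (1857 and 2065 genes), and the total of 3701 became 2421 without WT replicate 3. Changes in DKO and in PRC1-CD, which share no library, overlapped. Of 12428 genes tested in both, 1024 were higher in both against 301 for independent lists (odds ratio 12.2, 95% interval 10.9 to 13.7), and 368 were lower in both against 83.2 (odds ratio 10.4, 95% interval 8.83 to 12.2, Fisher's exact adjusted p = 5.34e-164). Genes higher in PRC1-CD and lower in DKO, or the reverse, numbered 63 and 13. Mt1, Rbm46, Syce1, Phlda2 and Rbms1 were among the shared higher genes.

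**Figure D2:**
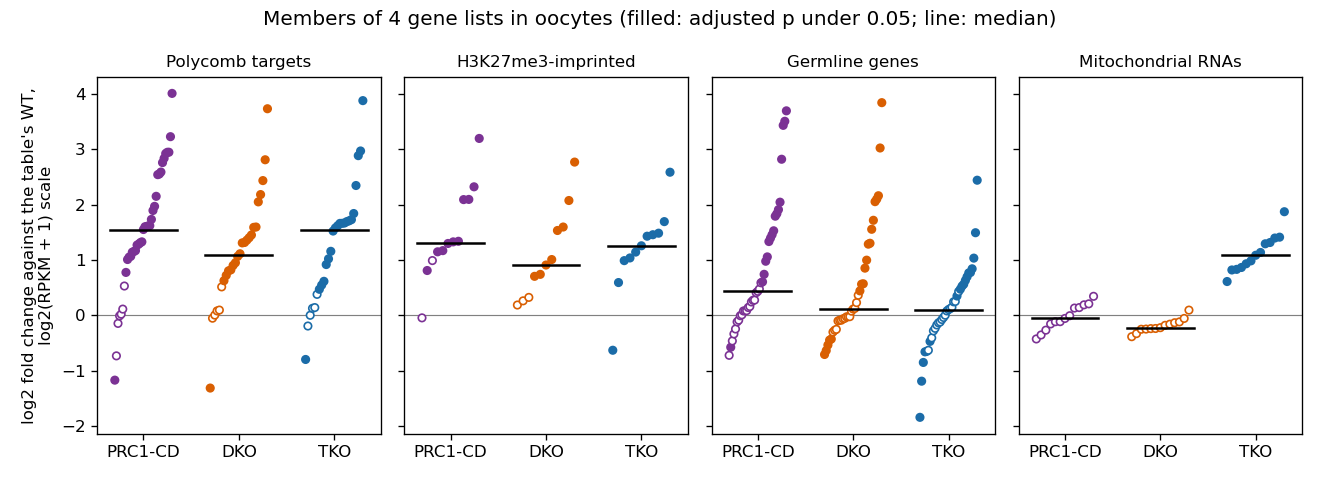
Log2 fold change of the members of 4 gene lists in PRC1-CD, DKO and TKO oocytes against the WT of the same table, on the log2(RPKM + 1) scale. Filled points passed the adjusted p and lines are medians. Polycomb targets have medians of 1.55, 1.09 and 1.55 over the 37, 26 and 26 of 114 members that passed the filter. Members silent in WT pass it only by rising in a mutant group. All 13 mitochondrial RNAs are higher in TKO. No median of a called list changed sign under the other scalings.

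TKO oocytes, which also lack MLL2, were compared with WT. Mt1 reached 1690 ± 303 RPKM (log2 change 8.79 ± 0.11, n = 3 each, adjusted p = 3.69e-11). Plac1 rose by 4.64 ± 0.28, the chemokine gene Ccl2 by 4.61 ± 0.31, Defb41 by 4.09 ± 0.37 and Lbx2 by 4.06 ± 0.14. The imprinted genes Cdkn1c, an inhibitor of the cell cycle, and Igf2, a growth factor, rose by 3.71 ± 0.13 and 3.70 ± 0.22. Rnu7 is listed at 0 in the WT libraries and averaged 56.0 ± 31.8 RPKM in TKO, and Rnaset2b rose by 4.68 ± 0.31. The largest falls after Pcgf1 were BC052688 (-5.13 ± 0.51) and members of the X-linked Xlr family: Xlr3c (-5.04 ± 0.20), Xlr5c (-4.83 ± 0.42), Xlr4b (-4.77 ± 0.13), Xlr4a (-3.95 ± 0.12) and Xlr4c (-3.89 ± 0.13). Zfp708 and the X-linked genes Fmr1nb and Lage3 followed, with changes between -3.75 and -3.74.

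Of the 26 of 114 Polycomb targets that passed the filter, 20 rose and 1 fell in TKO oocytes, with the limit given for DKO. The counts were the same adjusted over the list alone (camera adjusted p = 2.77e-06, and adjusted p = 0.265 with an estimated correlation). Hoxd1 rose by 2.97 ± 0.13 and Irx2 by 2.34 ± 0.13. Genes imprinted through maternal H3K27me3, of which 11 of 31 passed the filter, had 10 higher and 1 lower. The counts were again the same adjusted over the list alone (camera adjusted p = 0.000849, and adjusted p = 0.265 with an estimated correlation). Rbms1 (2.58 ± 0.17), Bmp7 (1.69 ± 0.13), Sall3 (1.48 ± 0.18), Enc1 (1.45 ± 0.15), Bbx, Matn1, Etv6, Runx1, Slc38a1 and Epas1 rose, and the long noncoding RNA Platr20 fell by 0.63. In the p53 and apoptosis list 13 rose and 1 fell of 21, the same adjusted over the list alone (adjusted p = 0.0122, and adjusted p = 0.299 with an estimated correlation), with Btg2 and Ddit3 up by 1.88 ± 0.11 and 1.34 ± 0.10 and the pro-apoptotic gene Bax down by 0.99 ± 0.09. Primitive endoderm genes had 8 of 10 higher and 1 lower (9 and 1 adjusted over the list alone; adjusted p = 0.0315, and adjusted p = 0.773 with an estimated correlation), among them Gata4 (1.66 ± 0.20) and Lamb1 (0.98 ± 0.10). Genes of the 2-cell stage had 1 higher and 5 lower of 10, the same adjusted over the list alone (adjusted p = 0.0294, and adjusted p = 0.483 with an estimated correlation), with Zfp809 down by 1.36 ± 0.15 and Zscan4d by 0.75 ± 0.16.

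All 13 mitochondrial transcripts rose in TKO oocytes, over all genes and adjusted over the list alone (adjusted p = 0.000255, and adjusted p = 0.812 with an estimated correlation), ND3 and ND2 by 1.87 ± 0.15 and 1.41 ± 0.18. The mitochondrial share of the total was 0.967 ± 0.0899% in WT, 0.826 ± 0.0885% in DKO and 1.89 ± 0.429% in TKO, and it stands beside every TKO list count given here. With mitochondrial transcripts removed and the libraries rescaled, 3972 genes were higher and 2572 lower in TKO.

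The lists not called in TKO oocytes held strong single changes. Klf4 and Sox2 rose by 3.33 ± 0.13 and 2.40 ± 0.14 while Dppa4 fell by 2.87 ± 0.35 among 17 pluripotency genes (5 higher, 6 lower, adjusted p = 0.577). Trophectoderm genes had 9 higher and 4 lower of 18 (adjusted p = 0.194), including Id2 (2.43 ± 0.12) and Atp1b1 (1.75 ± 0.10). Germline genes had 12 higher and 6 lower of 35 (adjusted p = 0.941), with Meioc up by 2.44 ± 0.21 and Tex15, a meiotic recombination gene, down by 1.84 ± 0.11. Of 46 X-linked housekeeping genes 9 were higher and 9 lower (adjusted p = 0.542; 8 and 11 with quantile normalization, 7 and 12 with median-ratio scaling), and the falls of Idh3g (-2.80 ± 0.16), Prdx4 (-2.22 ± 0.14), Ssr4 (-2.12 ± 0.08) and Atrx (-1.33 ± 0.08) were the clearest. The PRC1 list had 14 higher and 4 lower of 30 (adjusted p = 0.410), with Bcor up by 1.91 ± 0.12 and Kdm2b by 1.19 ± 0.13. Among 18 genes imprinted through DNA methylation 5 were higher and 2 lower (adjusted p = 0.495; 3 and 3 under both other scalings), and Snrpn fell by 1.35 ± 0.14. Oocyte and maternal-effect genes had 9 higher and 14 lower of 49 (adjusted p = 0.285), and 3 members changed sign with quantile normalization. Counts higher and lower were 8 and 1 of 16 for DNA methylation genes (adjusted p = 0.369, with 1 member changing sign under quantile normalization), 10 and 2 of 21 for MLL and COMPASS genes (adjusted p = 0.484), 6 and 2 of 13 for PRC2 (adjusted p = 0.773), 5 and 2 of 10 for granulosa markers (adjusted p = 0.504) and 2 and 0 of 5 for stroma and blood markers (adjusted p = 0.994).

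Altogether 4013 genes were higher and 2592 lower in TKO than in WT oocytes, and 718 and 550 of these by at least 2-fold. The share of higher genes of 60.8% became 51.3% with quantile normalization (3244 and 3085) and 50.6% with median-ratio scaling (3263 and 3189). With PRC1-CD, 896 higher genes were shared against 531 for independent lists (odds ratio 2.87, 95% interval 2.58 to 3.18) and 341 lower genes against 149 (odds ratio 3.82, 95% interval 3.26 to 4.46). With DKO, which has the same WT libraries, 1257 higher genes were shared against 702 for independent lists and 722 lower genes against 292, where simulated groups without an effect, which have almost no calls to share, shared 0. Over 12873 genes, which are not independent replicates, the fold changes of DKO and TKO had a correlation of 0.489 against 0.500 without an effect and a covariance of 0.165 against 0.0135. With 3 WT libraries the controls could not be split, so part of these excesses may come from the shared controls.

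TKO oocytes were set against DKO oocytes to ask which DKO changes depend on MLL2. Pcgf1 did not differ (12.2 ± 1.52 against 12.3 ± 1.47 RPKM, adjusted p = 0.958), Kmt2b was lower by -1.20 ± 0.11 (adjusted p = 2.82e-05) and Pcgf6 higher by 0.33 ± 0.09 (adjusted p = 0.0160). Genes that had risen in DKO were among the largest falls. Syce1 stood at a mean of 44.1 RPKM in DKO and 2.44 ± 0.377 in TKO (log2 change -3.72 ± 0.12, adjusted p = 3.00e-08, n = 3 each), close to the 2.17 ± 0.361 of WT. The crossover gene Ccnb1ip1 fell by 4.69 ± 0.13, from 41.8 ± 5.37 to 0.653 ± 0.0321 RPKM, and Mad2l1bp, which silences the spindle checkpoint, by 4.28 ± 0.09. Xlr3c (-4.91 ± 0.20), Xlr4b, Xlr4c, Fmr1nb, Arxes2, Ccdc172 and Mocs2 also fell, the last from 84.9 ± 4.85 to 5.79 ± 0.650 RPKM. Among the genes that rose, Krt79 increased by 4.07 ± 0.27, Iqcf1 by 3.62 ± 0.80, Defb41 by 3.24 ± 0.37, Ptgds by 3.16 ± 0.30 and Pdpn by 3.12 ± 0.35, and Ccl2, Plac1, Fshr, Ly6a and Vmn1r132 by between 2.49 and 2.67.

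Of 2251 genes higher in DKO, 951 (42.2%) were lower in TKO than in DKO. In TKO, 573 of these did not differ from WT, 172 remained above it and 206 fell below it. Of 1450 genes lower in DKO, 622 (42.9%) were higher in TKO than in DKO, and 406, 50 and 166 of these were not different from WT, still below it and above it. Another 298 and 188 genes moved further away. Among all 12873 genes 2811 were lower and 3444 higher in TKO than in DKO, a background these returns include. Simulated data in which TKO equals DKO gave a mean of 0.05 returning genes in either direction, and data in which TKO equals WT gave 84.4% and 79.5%. The first setting has no differences between TKO and DKO, so its low value was fixed and does not stand for that background. Genes chosen in the PRC1-CD set avoid the shared libraries. Over 1726 genes higher in PRC1-CD the median log2 change was 0.60 in DKO and 0.48 in TKO. Of these genes 56.9% had a lower value in TKO than in DKO, called or not. Without a filter on low values these medians were 0.28 and 0.19. Over 723 genes lower in PRC1-CD the medians were -0.37 and -0.29, and 54.4% had a higher value in TKO than in DKO. Their median log2 difference between TKO and DKO was 0.037, against 0.036 over all genes. By this median the lower genes show no return beyond the general shift, and 211 of them were called higher and 146 lower in TKO than in DKO. Over the genes higher in PRC1-CD the median difference was -0.11, on the other side of the 0.036 over all genes. Of these, 558 were called lower and 346 higher. The share over all genes was not computed.

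**Figure D3:**
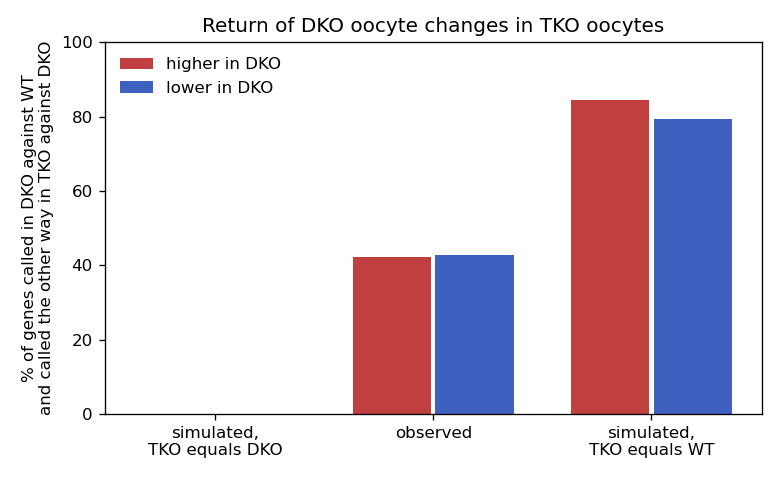
Share in percent of genes called higher (red) or lower (blue) in DKO than in WT oocytes that were called in the other direction in TKO against DKO. The observed bars stand at 42.2% and 42.9%, and those of simulated data at 84.4% and 79.5% where TKO equals WT and near 0 where TKO equals DKO. The last setting has no differences to count, whereas among all 12873 genes 2811 were lower and 3444 higher in TKO than in DKO.

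The mitochondrial list was the only list called between TKO and DKO oocytes, with 13 of 13 higher over all genes and adjusted over the list alone (adjusted p = 5.75e-06, and adjusted p = 0.773 with an estimated correlation). ND3 rose by 1.78 ± 0.15. Germline genes had 9 higher and 16 lower of 35 (adjusted p = 0.194), with Majin (-2.91 ± 0.22) and Tex15 (-2.28 ± 0.11) down and Sycp2 up by 1.41 ± 0.09. Genes imprinted through maternal H3K27me3 had 5 higher and 2 lower of 11 (adjusted p = 0.780). Matn1 (1.07 ± 0.20), Runx1 (0.77 ± 0.14), Slc38a1, Enc1 and Etv6 rose, and Platr20 (-1.37 ± 0.13) and Sall3 (-0.59 ± 0.18) fell. Polycomb targets had 11 higher and 7 lower of 26 (adjusted p = 0.454), with Foxc1 up by 0.95 ± 0.13 and Irx1 and Msx2 down by 1.21 ± 0.16 and 1.06 ± 0.13. X-linked housekeeping genes had 9 higher and 13 lower of 46 (adjusted p = 0.324), among the latter Idh3g (-2.91 ± 0.16) and Prdx4 (-2.90 ± 0.14). No other list passed, with adjusted p between 0.130 for MLL and COMPASS genes and 0.900 for p53 and apoptosis genes. In all, 3444 genes were higher and 2811 lower, 391 and 588 of these by at least 2-fold, and with median-ratio scaling 3068 and 3165.

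Maternal DKO morulae were compared with WT morulae to ask what is passed on to the embryo. The labels call these embryos maternal mutants, so the deleted genes need not be absent from them. Pcgf1 fell from 23.4 ± 5.32 to 9.94 ± 3.31 TPM (log2 change -1.19 ± 0.21, n = 10 each, adjusted p = 0.00184). Pcgf6 stood at 23.0 ± 5.61 and 20.3 ± 6.01, Kmt2b at 6.69 ± 2.87 and 9.55 ± 2.42, Ring1 at 6.35 ± 1.32 and 6.998 ± 2.72, and Rnf2 at 31.5 ± 9.32 and 30.1 ± 7.73, none of which passed. X-linked genes stood out among the falls. The glycolytic gene Pgk1 fell by 3.80 ± 0.47, from 48.2 ± 20.3 to 3.25 ± 3.19 TPM (adjusted p = 1.09e-05), and Msn, which links the membrane to actin, by 3.79 ± 0.41 (adjusted p = 1.38e-06). Pls3 (-2.78 ± 0.34), Xlr3a (-2.77 ± 0.41), Plac1 (-2.74 ± 0.47), Il2rg, Xlr3b and the DNA repair gene Apex2 (-2.25 ± 0.29) lie on the X chromosome as well, whereas Cphx1 and Nat2 do not. Xist, the noncoding RNA that silences the X chromosome (chromosome X, 103460373 to 103483233), rose from 23.7 ± 22.2 to 59.0 ± 30.7 TPM (1.81 ± 0.47, adjusted p = 0.0393). Its neighbour Ftx rose by 1.70 ± 0.34 (adjusted p = 0.00761). Ly6c1 (1.93 ± 0.45), Lbx2 (1.38 ± 0.32), Mov10l1 (1.31 ± 0.33), Snora21, Bglap2, Lat2, Dnase1 and Plod1 were the other risers of the top 10.

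On the X chromosome 66 of 407 tested genes were lower in DKO morulae and 2 higher, against 115 lower of 12274 elsewhere (odds ratio 20.4, Fisher's exact p = 1.21e-52, two-sided). With the Y-linked score as a covariate 67 were lower and 2 higher, and in libraries with Y-linked transcripts only 5 and 0 of 397. Genes are not independent replicates, so this Fisher's exact p does not measure the spread between libraries. Tests over libraries are given below with the X minus autosome score. The median log2 change was -0.43 for X-linked genes and -0.09 for the others. The X-linked housekeeping list had 8 lower and 0 higher of 51 (13 lower and 1 higher adjusted over the list alone; adjusted p = 0.000144, and adjusted p = 0.813 with an estimated correlation). Besides Pgk1 it included Rlim, whose product promotes Xist expression (-1.54 ± 0.27), Morf4l2 (-0.94 ± 0.20) and Atp7a (-0.93 ± 0.18). Of 25 genes imprinted through maternal H3K27me3, Xist and Platr4 (1.22 ± 0.27, adjusted p = 0.0166) rose and 0 fell, the same adjusted over the list alone (adjusted p = 0.0304, and adjusted p = 0.773 with an estimated correlation). Mitochondrial transcripts had a median of 0.44 with 0 of 13 called singly or adjusted over the list alone (adjusted p = 0.000282, and adjusted p = 0.773 with an estimated correlation), beside mitochondrial shares of 7.72 ± 2.36% in WT and 10.3 ± 5.85% in DKO. DKO replicate 7 alone had a share of 25.0%, against 14.6% for the next DKO library. In the lists not called, Plac1 fell in the trophectoderm list (0 higher and 1 lower of 32, adjusted p = 0.134), Yaf2 beside Pcgf1 in the PRC1 list (-1.34 ± 0.25; 0 and 2 of 35, adjusted p = 0.448), and Msx2 and Pitx1 among Polycomb targets (-1.37 ± 0.32 and -0.88 ± 0.23), where Meis1 rose by 0.77 ± 0.21 (1 and 2 of 25, adjusted p = 0.994). Mov10l1 was the only germline gene called of 32 (adjusted p = 0.285). The other lists had 0 members called, with adjusted p between 0.124 for primitive endoderm and 0.784 for DNA methylation genes.

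In total 43 genes were higher and 184 lower in DKO than in WT morulae among 13056 tested, and 19 and 101 of these by at least 2-fold. The share of higher genes of 18.9% was 40.4% both with quantile normalization (103 and 152) and with median-ratio scaling (99 and 146). A group of 5 libraries, 1 WT, 2 DKO and 2 TKO, lay above a cut of 40 on the first principal component and is described as standing apart. This component held 24.5% of the variance, and the group had low trophectoderm scores. The WT library lay just past the cut at 40.8, DKO replicate 6 below it at 31.4, and the mutant libraries of the group at 67.1 or more. Without these 5 libraries 126 genes were higher and 375 lower, and 210 of the 227 genes were kept. Of 9375 genes tested at both stages 4 were higher in DKO at both against 4.20 for independent lists (odds ratio 0.942, 95% interval 0.234 to 2.82, Fisher's exact p = 1), among them Lbx2 and Mov10l1, and 19 were lower at both against 14.4 (odds ratio 1.38, 95% interval 0.799 to 2.25, p = 0.206). Of the genes named, Lbx2 lies near the deleted Pcgf1, and Pcgf1 itself is among the 19 lower at both stages. Another 32 genes, 12 of them X-linked, were higher in DKO oocytes and lower in DKO morulae, against 26.6 for independent lists (odds ratio 1.26, 95% interval 0.823 to 1.88, Fisher's exact p = 0.238).

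Maternal TKO morulae were likewise compared with WT. Pcgf1 stood at 14.9 ± 6.49 TPM (log2 change -0.70 ± 0.21, n = 10 each, adjusted p = 0.115), Pcgf6 at 17.6 ± 4.02, Kmt2b at 6.87 ± 3.29, Ring1 at 5.41 ± 2.22 and Rnf2 at 29.0 ± 8.04, and none passed. X-linked genes again made up the falls of the top 10: Xlr3b (-3.25 ± 0.53), Fmr1nb (-2.89 ± 0.54), Xlr3a (-2.66 ± 0.41), Trap1a (-2.65 ± 0.37), Pgk1 (-2.62 ± 0.47, adjusted p = 0.00444), Msn (-2.57 ± 0.41), Xlr5b, Il2rg, Hsd17b10 (-1.94 ± 0.39) and Xlr3c. The phospholipase gene Pla2g7 rose by 2.11 ± 0.43, Ly6c1 by 1.91 ± 0.45 and the noncoding RNAs Platr4 and Lncenc1 by 1.79 ± 0.27 (adjusted p = 0.000872) and 1.75 ± 0.30. Mxra8, Ly6a, Mir17hg, Lix1l, Snora81 and Rabl2 rose by between 0.97 and 1.14. Xist stood at 37.5 ± 19.2 TPM (1.16 ± 0.47, adjusted p = 0.266).

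In TKO morulae 31 of 407 X-linked genes were lower and 0 higher, against 20 lower of 12274 elsewhere (odds ratio 50.4, Fisher's exact p = 6.95e-34, two-sided). With the Y-linked score as a covariate 24 were lower and 2 higher, and in libraries with Y-linked transcripts only 9 and 2 of 397. A pseudocount of 0.1 gave 9 lower and 0 higher, and leaving out the libraries standing apart gave 68 and 1 of 396, beside 92 lower of 12265 elsewhere. As in DKO morulae, genes are not independent replicates in the Fisher's exact test, and tests over libraries are given below. The X-linked housekeeping list had 5 lower of 51 (19 lower adjusted over the list alone; adjusted p = 7.72e-11, and adjusted p = 0.599 with an estimated correlation), including Rlim (-1.17 ± 0.27) and Ubl4a (-1.11 ± 0.26). With the covariate 3 of its members were lower, and its median moved from -0.49 to -0.25. With a pseudocount of 0.1, 0 of its members were lower. Of the genes imprinted through maternal H3K27me3 only Platr4 passed of 25 (3 higher adjusted over the list alone; adjusted p = 0.00129, and adjusted p = 0.599 with an estimated correlation). Trophectoderm genes had a median of -0.36, with Ly6a higher and 0 lower of 32 (1 and 3 adjusted over the list alone; adjusted p = 0.0269, and adjusted p = 0.813 with an estimated correlation). With a pseudocount of 0.1 this list had adjusted p = 0.0624 and was not called. Trophectoderm scores, which move with the libraries standing apart, were 6.00 in WT, 5.49 in DKO and 5.57 in TKO. Mitochondrial transcripts had a median of 0.40 (0.21 with quantile normalization) with 0 of 13 called singly or adjusted over the list alone (adjusted p = 8.52e-05, and adjusted p = 0.773 with an estimated correlation), beside a mitochondrial share of 10.5 ± 5.03%. Every other list had 0 members called, with adjusted p between 0.130 for germline genes and 0.994 for primitive endoderm. Altogether 23 genes were higher and 51 lower, 10 and 38 of these by at least 2-fold, and the share of higher genes of 31.1% became 43.8% with quantile normalization (60 and 77) and 42.3% with median-ratio scaling (52 and 71). Without the libraries standing apart 126 genes were higher and 162 lower, and 69 of the 74 were kept.

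Between oocytes and morulae of the TKO genotype, 18 genes were lower at both stages against 7.14 for independent lists (odds ratio 3.85, 95% interval 1.93 to 7.62, Fisher's exact p = 6.01e-05), among them the X-linked Xlr3b, Xlr3a, Xlr5b, Xlr3c and Fmr1nb. Near-identical Xlr copies are not independent genes in this test. X-linked genes were also lower more often than others at both stages, so the excess need not hold for other genes. Higher at both were 7 against 3.93 (odds ratio 2.88, 95% interval 0.787 to 11.5, p = 0.0690), among them Ly6a, Pla2g7, Lix1l and Snora81. DKO and TKO morulae, compared with the same WT libraries, shared 6 higher genes against 0.0758 for independent lists and 26 lower genes against 0.719, and simulated groups without an effect, which have almost no calls to share, shared 0. Their fold changes had a covariance of 0.104 over genes, against 0.0374 without an effect, and a correlation of 0.689 against 0.502. With the WT libraries split between the comparisons the covariance was 0.0805, and too few genes were called for the shared calls to be compared.

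TKO and DKO morulae differed in few genes. Rabl2 rose by 1.25 ± 0.18, from 8.28 ± 2.60 to 20.6 ± 4.32 TPM (adjusted p = 0.000666, n = 10 each), Platr5 by 1.49 ± 0.28 and Lonrf3 by 1.03 ± 0.20, and Ecel1 rose too. Lncenc1 is listed at 0 in the DKO libraries and averaged 3.87 ± 2.67 TPM in TKO. The histone gene Hist1h2ai fell by 1.23 ± 0.26, from 175 ± 65.4 to 71.9 ± 28.8 TPM. In all 6 genes were higher and 3 lower, 5 and 3 of these by at least 2-fold, and 867 genes had an unadjusted p under 0.05. Lists of the 2-cell stage (median -0.23, 0 of 19 called, adjusted p = 0.00697, and adjusted p = 0.773 with an estimated correlation), of primitive endoderm (median -0.22, 0 of 19, adjusted p = 0.0243, and adjusted p = 0.782 with an estimated correlation) and of X-linked housekeeping genes (median -0.11, 0 of 51, adjusted p = 0.0304, and adjusted p = 0.813 with an estimated correlation) passed on the side of lower values. Adjusted over the list alone, 0 members of these passed. The direction of the X-linked list reversed when Y-linked transcripts, present in 3 DKO and 8 TKO libraries, were taken into account: its median was 0.13 with the Y-linked score as a covariate (camera p = 0.0276, and p = 0.515 with an estimated correlation) and 0.11 in libraries with Y-linked transcripts only (camera p = 0.0255, and p = 0.341 with an estimated correlation). Without the libraries standing apart the median of that list was 0.00315 (camera p = 0.165). The remaining lists were not called, with adjusted p from 0.0808 for p53 and apoptosis genes to 0.994 for mitochondrial transcripts. Whether DKO changes return in TKO morulae was measured on separate libraries. Over 8 genes lower in DKO among odd-numbered replicates, 6 of them X-linked, the medians in even-numbered ones were -2.38 in DKO and -2.06 in TKO. Over 18 genes chosen on even-numbered replicates, 9 of them X-linked, they were -1.50 and -1.19 in odd-numbered ones. Without a filter on low values 0 genes could be chosen on either set of replicates. On odd-numbered replicates quantile normalization gave 14 genes with medians of -1.56 in DKO and -1.22 in TKO, and a pseudocount of 0.1 gave 0 genes.

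Xist depends on the sex of the embryo, which the labels do not give, so the libraries were also split by Y-linked transcripts, a choice made after the data were seen, whereas the Y-linked score as a covariate was planned. These were present in 5 WT, 3 DKO and 8 TKO libraries (mean log2 score of at least 2.64, against at most 0.174 in the others). With the Y-linked score as a covariate Xist rose by 1.42 ± 0.32 in DKO (adjusted p = 0.0198) and by 1.72 ± 0.32 in TKO (adjusted p = 0.00659). Among libraries with Y-linked transcripts, Xist stood at 5.59 ± 3.87 TPM in WT, 27.5 ± 2.99 in DKO and 33.3 ± 17.4 in TKO. Over 12 exact permutation tests, two-sided, DKO against WT gave p = 0.0179 (adjusted p = 0.0429) and TKO against WT p = 0.000777 (adjusted p = 0.00932), in both cases the smallest p these numbers of libraries allow, and every mutant library lay above every WT library. Among libraries without them Xist was 41.8 ± 16.7 TPM in WT and 72.5 ± 26.5 in DKO (exact permutation p = 0.0240, adjusted p = 0.0480), and 54.2 ± 22.7 in the 2 TKO libraries. For the X minus autosome score, the WT mean of each gene was first subtracted from its log2 values. The score is the median over X-linked genes, without Xist, minus the median over autosomal genes. It was lower than in WT by -0.37 in DKO (permutation p = 0.0112) and by -0.46 in TKO (permutation p = 7.58e-05), whereas TKO and DKO differed by -0.09 (permutation p = 0.491). That last difference was 0.17 among libraries with Y-linked transcripts (exact permutation p = 0.158, adjusted p = 0.236) and 0.01 among the others (exact permutation p = 0.944, adjusted p = 0.944). Within libraries with Y-linked transcripts the differences from WT were -0.50 in DKO (exact permutation p = 0.0179, adjusted p = 0.0429) and -0.33 in TKO (exact permutation p = 0.00311, adjusted p = 0.0186). Within those without, DKO differed by -0.42 (exact permutation p = 0.00631, adjusted p = 0.0253), and the 2 TKO libraries by -0.41, which did not pass (exact permutation p = 0.0476, adjusted p = 0.0816).

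**Figure D4:**
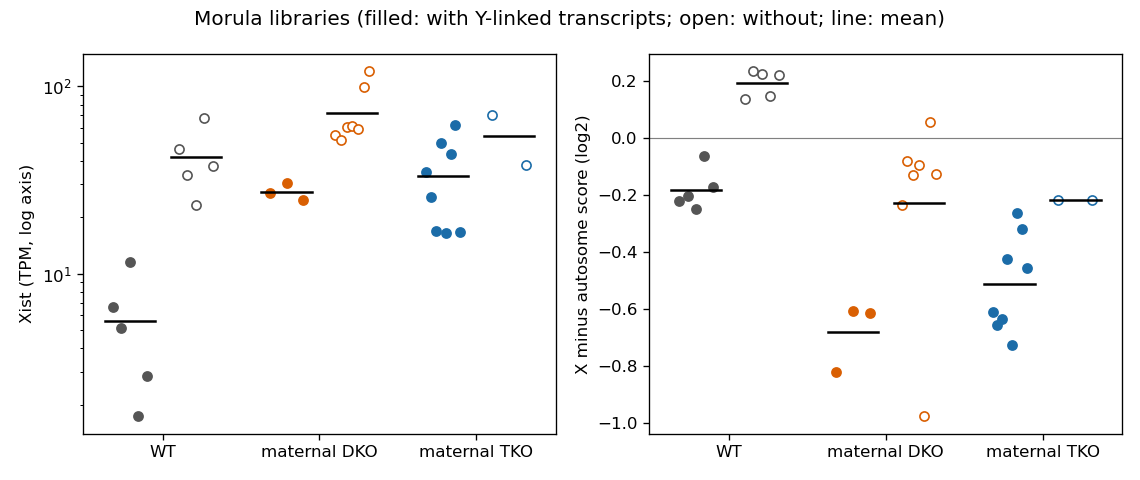
Xist (TPM, log axis) and the X minus autosome score (log2) of each morula library by genotype, filled where Y-linked transcripts were present and open where not, with lines at the means. Xist reaches 11.6 at most in WT libraries with Y-linked transcripts and lies at 16.5 or more in the mutant ones.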

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

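The tests of the patterns weighed here were chosen only after the results were seen, except the fit of Xist with the Y-linked score, which was planned. Morula values were compared within each group of 10 libraries, and a library was picked out where its gap to the nearest other value took up an unusually large share of the group's range. Chance flags about 1 in 20 groups, and 18 of 146 were picked out here. Several libraries return in these values, so they are not independent.

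WT replicate 9 lay apart in its trophectoderm score (gap 0.515 of the range), the first principal component (0.636), Plac1 (0.481), Pla2g7 (0.517) and Platr5 (0.477). DKO replicate 7 had a mitochondrial share of 25.0% against 14.6% for the next (0.529), a share of 41.7% in its 50 highest genes against 32.0% (0.510), and the lowest Xlr3a (0.495). TKO replicate 6 had 18832 genes above 0 against 17458 for the next (0.573). TKO replicate 8 lay apart in its trophectoderm score (0.487) and Platr4 (0.562), and TKO replicate 9 in Rnf2 (0.729) and Hsd17b10 (0.649). Single values stood out for Fmr1nb in WT replicate 3 (0.716), Xlr5b in WT replicate 8 (0.585), Lbx2 in DKO replicate 3 (0.566), Pla2g7 in DKO replicate 9 (0.638) and Hist1h2ai in DKO replicate 5 (0.539).

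The Xist change was also fitted against the Y-linked score. Per unit of the score the gain was larger by 0.42 ± 0.17 in DKO (limma p = 0.0195) and by 0.62 ± 0.17 in TKO (limma p = 0.00105), but with adjusted p = 1 and 0.904 over all genes a dependence did not pass the threshold. Of the genes called in opposite directions in oocytes and morulae, 32 for DKO and 9 for TKO, 3 had groups without overlap at both stages, and the difference between stages was not tested. Pgk1 was higher in DKO oocytes (0.43) and lower in DKO morulae (-3.80). C77370, named after its values were seen, was higher in DKO oocytes (0.66) and lower in DKO morulae (-1.31). Tcf12, named for the same reason, was higher in TKO oocytes (0.42) and lower in TKO morulae (-1.04).

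X-linked genes were lower in mutant morulae. Unequal shares of male and female embryos are argued against as the whole cause: among libraries with Y-linked transcripts the X minus autosome score of TKO was lower than that of WT by -0.329 (exact permutation p = 0.00311). The libraries standing apart are argued against too as the whole cause. Without them 83 of 396 X-linked genes were lower in DKO, against 286 of 12265 elsewhere. With all libraries these were 66 of 407 and 115 of 12274, so the calls rose more elsewhere than on the X chromosome and the excess was smaller. Which effect of the maternal genotypes underlies the fall was not tested. Separate crosses or litters of the genotypes were not tested and stay open.

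Granulosa markers were higher in PRC1-CD oocytes. RNA from granulosa or cumulus cells is argued against, because the highest mean of Amh, Foxl2, Inhba, Vim, Krt18, Gja1 and Fst was 0.51 RPKM in PRC1-CD (Vim, 0.055 in PRC1-WT), against 15.3 for Fshr. Of the 31 markers 21 were below 1 RPKM in PRC1-CD, while Cyp19a1 stood at 17.2 in both groups. Krt8 went from 1.43 in PRC1-WT to 39.9 in PRC1-CD and Ptgs2 from 0.12 to 5.21. Whether the rise is an effect of the lost PRC1 activity in the oocyte or of a difference in stage or strain between the groups was not tested.

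Rnaset2b was lower in PRC1-CD and higher in DKO oocytes. Division of reads between copies stays open: the sum of Rnaset2a and Rnaset2b changed by -0.0398 on the log2 scale in DKO, and by -0.35 in PRC1-CD. A strain variant stays open as well, since 9 of 30 morulae, 4 WT, 2 DKO and 3 TKO, had high values of at least 72.3 TPM and the others at most 15.9. Both may act together, and an effect of the genotypes is not needed by these values but was not excluded.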

How the results depend on the processing

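The alternatives without the libraries standing apart, with Y-linked transcripts only and without mitochondrial transcripts were chosen after the data were seen, and the others were planned. Of 8908 values of 657 named gene and comparison pairs under the alternatives, 8531 stayed on the same side of the threshold, 292 were no longer called, 85 became called and 0 values called on either side changed sign. Values that were not called could change sign: Xist in TKO against DKO morulae went from -0.65 to 0.30 with the Y-linked score as a covariate and to 0.11 in libraries with Y-linked transcripts. Depth is unknown, so counting error could not be separated from other spread, and genes near the minimum value are the least certain. Where no reason is given, the cause was not tested.

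A threshold of at least 2-fold calls fewer genes by construction: 1632 in PRC1-CD, 680, 1268 and 979 in the oocyte comparisons in the order DKO and TKO against WT and TKO against DKO, and 120 and 48 in DKO and TKO morulae. Under it 339 genes returned in TKO oocytes, the medians of TKO over genes higher and lower in PRC1-CD were 0.62 and -0.51, and the overlap of genes lower in DKO oocytes and morulae had an odds ratio of 6.32 from 3 genes. These 3 include the deleted Pcgf1 (-6.39 in oocytes and -1.19 in morulae) and Xlr5c (-1.79 and -1.45), of a family with near-identical copies. This odds ratio is therefore no measure of changes passed on to the embryo. Without a filter on low values, which raises the number of tests, the morula counts were 93, 32 and 5, and the medians over genes higher in PRC1-CD were 0.19 in TKO and 0.28 in DKO. A pseudocount of 0.1 gave 21 genes in TKO morulae and, in TKO oocytes, a median of 0.71 over genes higher in PRC1-CD. TKO morulae had 137 genes with quantile normalization and 123 with median-ratio scaling, and the TKO median over genes lower in DKO morulae was -1.22 with quantile normalization. There, 4 genes higher in DKO among even-numbered replicates had medians of 0.65 in DKO and 0.21 in TKO. Without a filter 0 genes could be chosen on odd-numbered or even-numbered replicates for that comparison, and with a pseudocount of 0.1 there were 0 on odd-numbered replicates. With only the groups compared in the fit, TKO morulae had 127 genes and TKO against DKO 4.

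With the Y-linked score as a covariate, the counts were 47 and 3, and Xist rose by 1.72 in TKO. In libraries with Y-linked transcripts only, the Xist difference was 2.30 in DKO, no longer past the threshold with fewer samples, and 2.41 in TKO, now past it. Without the libraries standing apart, DKO morulae had 501 genes and TKO morulae 288. With an estimated correlation 0 list tests were called.

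Leaving out 1 library gave 1238 to 1543 genes in PRC1-CD, where the lone library of a group is assumed to vary like the other group, and 2421 to 4211 in DKO oocytes, 2421 being without WT replicate 3. The labels do not say that replicate numbers pair the samples, and not every same-numbered pair correlated. Mean correlations were 0.0900, 0.00596 and 0.104 in the PRC1, oocyte and morula tables. In morulae 13 of 30 pairs were above 0.1, up to 0.58, and 9 matched their own number best, a hint from the data that some numbers share a source, which stays open. With a replicate block the counts were 607, 183 and 16 in the morula comparisons.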

Other observations

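The tests of the X-linked genes in oocytes and of the relation between Xist and X-linked expression were chosen only after the results were seen, and the splits of the samples were planned.

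X-linked genes were lower in TKO than in DKO oocytes more often than others, with 156 of 427 (36.5%) against 2572 of 12130 genes placed elsewhere (21.2%; odds ratio 2.14, Fisher's exact p = 1.47e-12, two-sided). Ssr4, which takes part in protein translocation, fell by 2.24 ± 0.08 and stood among them with Idh3g (-2.91 ± 0.16), Prdx4 (-2.90 ± 0.14) and the kinase gene Araf (-2.36 ± 0.15). Against WT, 118 of the 427 were lower in TKO (27.6% against 19.7%, odds ratio 1.56, p = 9.89e-05) and 41 in DKO (9.60% against 11.3%, odds ratio 0.832, p = 0.311). Genes are not independent replicates, and the mitochondrial share differed between these groups as well.

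The Xlr family alone is argued against as the source of this excess, because the odds ratio was 2.03 without its members (147 of 416 genes, Fisher's exact p = 8.81e-11). Whether X-linked genes depend on MLL2 in oocytes was not tested apart from other differences between the groups.

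A further hypothesis was that embryos with more Xist RNA have lower X-linked expression. Among the 8 TKO libraries with Y-linked transcripts Pearson's r between log2 Xist and the X minus autosome score was 0.71 (permutation p = 0.0551, adjusted p = 0.110), Spearman's rho was 0.76 (permutation p = 0.0368), and r was 0.51 without the 2 libraries farthest from the median. Among the 7 DKO libraries without Y-linked transcripts r was 0.31 (permutation p = 0.516, adjusted p = 0.516), rho 0.29 (permutation p = 0.556) and r -0.22 without the 2 farthest. Log2 Xist also went with the first principal component, on which some libraries stand apart (r 0.49 in these TKO and 0.95 in these DKO libraries, not tested). Neither of these 2 tests of the X minus autosome score passed the threshold, so the relation stays open. The r of both full groups was positive, where the hypothesis predicts a negative value.

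Other splits of the same libraries were counted for each comparison of at least 3 libraries per group. For the oocytes the 10 splits are too few for a share under 0.05. The real splits gave 3701, 6605 and 6255 changed genes in the order DKO against WT, TKO against WT and TKO against DKO, and the highest other split gave 2 in each. In morulae 100 splits were drawn. For DKO against WT the real split gave 227 genes and the highest other 7, and for TKO against WT 74 and 0, so that 1 of 100 splits, the real split, was as large. The splits assume exchangeable libraries, which the structure described below puts in doubt, so chance is not excluded. For TKO against DKO 4 of 100 splits gave at least the real 9 genes, a share under 0.05, but the highest gave 382. That split put DKO replicates 8 and 9 and TKO replicates 8 and 9, which stand apart from the rest, on the same side, so it points to a structure of the samples. These libraries share replicate numbers, as does WT replicate 9, and the splits treat all libraries as exchangeable, which the labels leave open.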
